A study of Homo sapiens with 12 samples.

How the data were processed

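RNA from MDA-MB-231 cells, a line derived from a breast cancer, and HCT116 cells, a line derived from a colon cancer, was sequenced after 3 treatments of each line. The treatments were control IgG, IgG with 100 µM hydrogen peroxide (H2O2), and an antibody called anti-Hsp60N with 100 µM H2O2, and the H2O2 exposure lasted 8 h. The name of the antibody points to Hsp60, the mitochondrial chaperonin encoded by HSPD1, and the labels do not say what the N stands for. Each of the 6 groups had 2 libraries, which makes 12 libraries. Per the labels' protocols, both lines were grown with 10% fetal bovine serum but in different media, so line and medium differ together. Cells were lysed in the buffer of a column kit for RNA, total RNA was the starting molecule, and libraries followed a standard Illumina protocol whose strand setting is not given in the sources used here.

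The deposited values were TPM, which are scaled to gene length and to the total of a library, per gene in 1 table of 23686 gene symbols, given to 2 decimals, with the same total in every library. The submitters' processing notes name bcl2fastq 2.20, STAR, RSEM and the genome build hg19, without stating the role or order of the tools; versions of STAR and RSEM and the gene annotation are not given in the sources used here. The reference at hand was another build, so no coordinates are given and it served for gene names alone: 4 list symbols were matched to older symbols in the table (TIGAR to C12orf5, CXCL8 to IL8, SC5D to SC5DL and CTSL to CTSL1). TPM keeps no read depth, so the sequencing depth of each library is unknown and no counting interval or floor could be given. A value of 0 in such a table can be a failed estimate, and genes with a group at 0 are described as listed at 0, with each library's value and no fold change. Each library was matched to its column by the label in its description, and 0 columns were left unmatched.

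From these values, log2(TPM + 1) was computed, so that a fold change is on the log2(TPM + 1) scale and understates the change of genes with low values. Genes with a TPM of at least 1 in at least 2 of the 12 libraries were kept, which left 13956 genes, and 4505 genes were at 0 in every library. The test was limma 3.58.1 (R 4.3.3) with a variance trend, two-sided, on 6 group means over all 12 libraries, with 6 residual degrees of freedom per gene, a prior of 4.63 degrees of freedom and Benjamini-Hochberg adjustment over all genes kept. An adjusted p under 0.05 was taken as the threshold. The 9 comparisons were H2O2 with IgG against IgG in each line, anti-Hsp60N with H2O2 against IgG with H2O2 in each line, anti-Hsp60N with H2O2 against IgG in each line, the difference between lines of the H2O2 change and of the antibody change, and the lines under IgG. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

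Gene lists were fixed from textbook knowledge, and 27 of 29 lists had at least 5 genes kept and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stand camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. The lists were targets of NRF2, p53 and NF-kappaB, immediate early genes, the ATF4 integrated stress response, the unfolded protein response of the endoplasmic reticulum, heat shock genes, mitochondrial chaperones and proteases, antioxidant enzymes, metallothioneins, nuclear genes of oxidative phosphorylation, DNA replication, mitosis, DNA repair, apoptosis, hypoxia and glycolysis, cholesterol synthesis, interferon response, autophagy and lysosome, ribosomal proteins, ribosome biogenesis, replication-dependent histones, a list of non-coding RNAs with SNHG1 and GAS5, transforming growth factor beta and matrix genes, and markers of epithelial, mesenchymal, and fibroblast or endothelial cells. Some genes stand on more than 1 list, among them SESN2 (p53 and ATF4) and SLC7A11 (NRF2 and ATF4). Immune markers, with 3 genes kept, and mitochondrially encoded genes were not analysed here. Of 104 list results past the threshold, 104 had a median, a mean and a test of the same sign.

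The genes named in the text followed a fixed rule. In each of the 4 comparisons of H2O2 with IgG or antibody with IgG within a line, the rule took the 10 highest and 10 lowest fold changes among genes past the threshold, with a mean TPM of at least 5 in 1 of the groups and libraries that do not overlap between groups. Where fewer than 5 passed in a direction, genes of smallest p were added up to 5 and are given as not passing. The rule also took up to 3 genes of smallest p per list past the threshold, HSPD1 in every comparison, 5 genes per direction in the other comparisons, and for the lines under IgG up to 3 markers per list of epithelial and mesenchymal genes. Some genes that the rule names are not reported here. Other named genes were chosen after their values were seen, and this is said where they appear. Genes with near-identical copies, and histone genes, are uncertain because the counting can split their reads.

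The groups, comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, limma without the trend, each line fitted alone, the replicate number as a block, and leaving out each library in turn. Leaving out 54 small RNA genes, and a block with exchanged numbers in HCT116, were added after seeing the data. The steps were tested on simulated data for H2O2 against IgG in MDA-MB-231, with 13956 genes and 50 genes changed at each size. The test recovered 18% of the genes changed by 0.25 log2, 92% at 0.5 and 100% at 1 and 2 log2, and 5 of 160 calls were false. With no change simulated in HCT116, 0 genes were called. A list of 25 genes shifted by 0.3 log2 was called, and 0 of 20 unchanged lists were. Simulated genes varied independently, so these runs cannot show how correlation between genes affects the list test.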

Results

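Gene expression was measured by RNA sequencing in 2 cancer cell lines, MDA-MB-231 from breast and HCT116 from colon, as TPM per gene. Each line was sampled under IgG, under IgG with H2O2, an oxidant, and under the anti-Hsp60N antibody with H2O2, with 2 libraries in each of the 6 groups. The design asks what 100 µM H2O2 over 8 h does to the transcriptome of each line, and how expression under H2O2 differs with the antibody. No group had the antibody without H2O2. An altered response to H2O2 therefore cannot be told from an antibody effect that needs no H2O2. Between 12411 and 12653 genes reached 1 TPM in a library, and the 10 most abundant genes held 6.53% to 7.49% of the TPM. Libraries of the same group correlated at 0.994 to 0.996 across genes (6 pairs), libraries of other groups of the same line at 0.984 to 0.995 (24 pairs), and libraries of different lines at 0.792 to 0.802 (36 pairs). Nothing states that the 2 replicates of a group came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

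Under IgG, the lines differed in their epithelial and mesenchymal genes. RAB25, a small GTPase of epithelial cells, stood at 127 ± 6.94 TPM (SD, n = 2) in HCT116 and 0.04 ± 0.0566 TPM in MDA-MB-231. ESRP1, an epithelial splicing regulator, stood at 81.4 ± 4.38 and 0.085 ± 0.0495 TPM. VIM, which encodes the intermediate filament vimentin, stood at 5.15 ± 0.12 TPM in HCT116 and 2534 ± 23.1 TPM in MDA-MB-231. TIMP3, an inhibitor of matrix proteases, stood at 0.6 ± 0.099 and 188 ± 15.6 TPM. Of 18 epithelial markers, 17 were higher and 1 lower in HCT116 (median log2 fold change 3.22, camera adjusted p = 6.7e-07, adjusted p = 0.0167 with an estimated correlation). Of 18 mesenchymal markers, 1 was higher and 16 lower (median -2.33, camera adjusted p = 6.16e-07, adjusted p = 0.0892 with an estimated correlation). Of 24 interferon response genes, 2 were higher and 21 lower (median -2.11, camera adjusted p = 6.16e-07, adjusted p = 0.0167 with an estimated correlation). Adjusted over the list alone, the counts of these 3 lists were the same. Across all 13956 genes, limma called 6348 higher and 5209 lower in HCT116, and 5701 higher and 5901 lower after median-of-ratios scaling. The median of all genes was 0.11 log2 higher in HCT116 with the TPM as deposited and -0.01 after median-of-ratios scaling.

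H2O2 raised HMOX1, the heme oxygenase induced by oxidative stress, in MDA-MB-231 from 29.7 ± 0.643 TPM (SD, n = 2) to 72.3 ± 2.72 TPM, a log2 fold change of 1.25 (SE 0.06, limma adjusted p = 4.5e-06). CDKN1A, the cell cycle inhibitor p21, rose from 125 ± 3.27 to 195 ± 5.44 TPM (log2 0.64, SE 0.04, limma adjusted p = 3.88e-05). PTGS2, the inducible cyclooxygenase, went from 3.85 ± 0.0566 to 7.26 ± 0.0141 TPM (log2 0.77, SE 0.09, limma adjusted p = 0.00126). Genes of mitosis fell: PLK1, a mitotic kinase, went from 174 ± 2.89 to 82.4 ± 2.46 TPM (log2 -1.07, SE 0.05, limma adjusted p = 4.81e-06). KIF20A, a kinesin of cytokinesis, went from 110 ± 0.339 to 42.1 ± 0.318 TPM (log2 -1.37). CCNB1, which encodes cyclin B1 (log2 -1.05), the mitotic kinases AURKA (log2 -0.96) and NEK2 (log2 -0.94), and the DNA helicase gene PIF1 (log2 -1.26) fell as well. HSPA1A (log2 0.81) and HSPA1B (log2 0.84), near-identical genes of inducible Hsp70 whose split is uncertain, rose, as did HSPA6, another Hsp70 gene (0.595 ± 0.0212 to 2.64 ± 0.424 TPM). Also called higher were SLC7A11, the cystine transporter (log2 0.70), and CCNE2, a G1/S cyclin (log2 0.60). HYAL3 (log2 0.71), PINLYP (log2 0.79) and the antisense gene TRAF3IP2-AS1 (log2 0.61), which cannot be told from its sense partner here, were called higher too. ALPP, a placental alkaline phosphatase (log2 -0.90), and FAM64A (log2 -0.90) were called lower. HYAL3 was lost without H2O2 replicate 1 (limma adjusted p = 0.157) or IgG replicate 2 (0.106). PINLYP was lost without IgG replicate 1 (0.13), H2O2 replicate 1 (0.0847) or H2O2 replicate 2 (0.15). TRAF3IP2-AS1 was lost without any 1 of the 12 libraries except IgG replicate 1 (up to 0.248 without H2O2 replicate 1).

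Of 25 mitosis genes in MDA-MB-231, 22 fell and 0 rose with H2O2 (25 fell adjusted over the list alone), with a median of -0.54 (camera adjusted p = 5.56e-45, adjusted p = 0.043 with an estimated correlation). DNA replication genes went the other way: 17 of 25 rose and 0 fell (21 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 5.35e-17, adjusted p = 0.043 with an estimated correlation). Among them MCM2, of the replicative helicase, rose from 50.4 ± 1.71 to 68.6 ± 0.339 TPM (log2 0.44), FEN1, the flap endonuclease, by log2 0.38, and RRM2, of ribonucleotide reductase, by log2 0.45. Of 27 NRF2 targets, 8 rose (11 adjusted over the list alone), among them TXNRD1, thioredoxin reductase (log2 0.52), and SRXN1, sulfiredoxin (log2 0.33). The list median was 0.11 (camera adjusted p = 1.4e-07, adjusted p = 0.043 with an estimated correlation). These 3 lists were the ones that also passed with an estimated correlation. Of 22 ATF4 genes 5 rose (9 over the list alone), including MTHFD2, a mitochondrial folate enzyme (log2 0.52), with a median of 0.16 (camera adjusted p = 0.000677, adjusted p = 0.135 with an estimated correlation). Of 25 DNA repair genes, 4 rose (6 over the list alone), with a median of 0.12 (camera adjusted p = 0.00412, adjusted p = 0.244 with an estimated correlation). The 3 Hsp70 genes were the members that rose among 18 heat shock genes (4 over the list alone, median 0.05, camera adjusted p = 0.0119, adjusted p = 0.446 with an estimated correlation).

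Smaller shifts in MDA-MB-231 passed at the preset correlation, each with few or no called members. The list median was 0.08 for 17 mitochondrial chaperones and proteases (0 called, 3 over the list alone, camera adjusted p = 0.0421, adjusted p = 0.244 with an estimated correlation). It was 0.07 for 22 ribosome biogenesis genes (0 called, 3 over the list alone, camera adjusted p = 0.0423, adjusted p = 0.446 with an estimated correlation). It was -0.04 for 20 cholesterol synthesis genes (1 fell, 2 over the list alone, camera adjusted p = 0.0358, adjusted p = 0.46 with an estimated correlation). It was -0.14 for 13 histone genes (0 called, camera adjusted p = 0.016, adjusted p = 0.181 with an estimated correlation) and -0.27 for 5 fibroblast or endothelial markers (0 called, 1 over the list alone, camera adjusted p = 0.00295, adjusted p = 0.135 with an estimated correlation). For epithelial markers it was -0.06 (1 of 18 fell, 4 over the list alone, camera adjusted p = 0.00412, adjusted p = 0.0825 with an estimated correlation). For mesenchymal markers it was -0.05 (0 of 18 called, 1 over the list alone, camera adjusted p = 0.0332, adjusted p = 0.407 with an estimated correlation). Leaving out IgG replicate 2 ended the calls for chaperones (camera adjusted p = 0.142), ribosome biogenesis (0.12), cholesterol synthesis (0.121) and mesenchymal markers (0.142). Leaving out H2O2 replicate 1 ended the same 4 (0.0892, 0.0892, 0.089 and 0.089) and histones (0.089). Without IgG replicate 1 the calls for histones (0.258), epithelial markers (0.054) and ribosome biogenesis (0.0558) ended. Without H2O2 replicate 2, those ended for chaperones (0.0716), ribosome biogenesis (0.0716) and cholesterol synthesis (0.0501). Median-of-ratios scaling ended chaperones and ribosome biogenesis (0.121 each).

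The other 14 lists did not pass in MDA-MB-231. The p53 targets had a median of 0.04 with 2 of 27 higher and 1 lower (camera adjusted p = 0.148). The NF-kappaB targets had 0.17 with 1 of 25 higher and 1 lower (camera adjusted p = 0.107). Antioxidant enzymes had 0 of 20 members called (median 0.01 and mean 0.02 with the test pointing down, camera adjusted p = 0.83), as had oxidative phosphorylation with 0 of 30 (median 0.03 and mean 0.01, test down, camera adjusted p = 0.83). The unfolded protein response (median 0.04, 0 of 16 called, camera adjusted p = 0.436) and the interferon response (median 0.05, 0 of 24 called, camera adjusted p = 0.83) did not pass either. Over all genes, limma called 371 of 13956, 181 higher and 190 lower, 10 of them by at least 2-fold. The split was 154 higher and 279 lower after median-of-ratios scaling, 157 and 242 after quantile normalization, and 29 and 57 with the line fitted alone, but 209 and 196 at a mean TPM of at least 5. Without IgG replicate 1 the count was 167 (58 higher and 109 lower), without IgG replicate 2 it was 184 (103 higher and 81 lower), and without H2O2 replicate 1 or 2 it was 122 or 116. Among the called genes SNORA51, a small nucleolar RNA, was at 21.5 and 28 TPM in the IgG libraries and listed at 0 in both H2O2 libraries. SNORA71C was at 14.9 and 19.3 TPM and listed at 0 in the same way. Its call was lost without any 1 of these 4 libraries (limma adjusted p = 0.168 and 0.153 without IgG replicate 1 or 2, and 0.19 and 0.214 without H2O2 replicate 1 or 2).

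**Figure D1:**
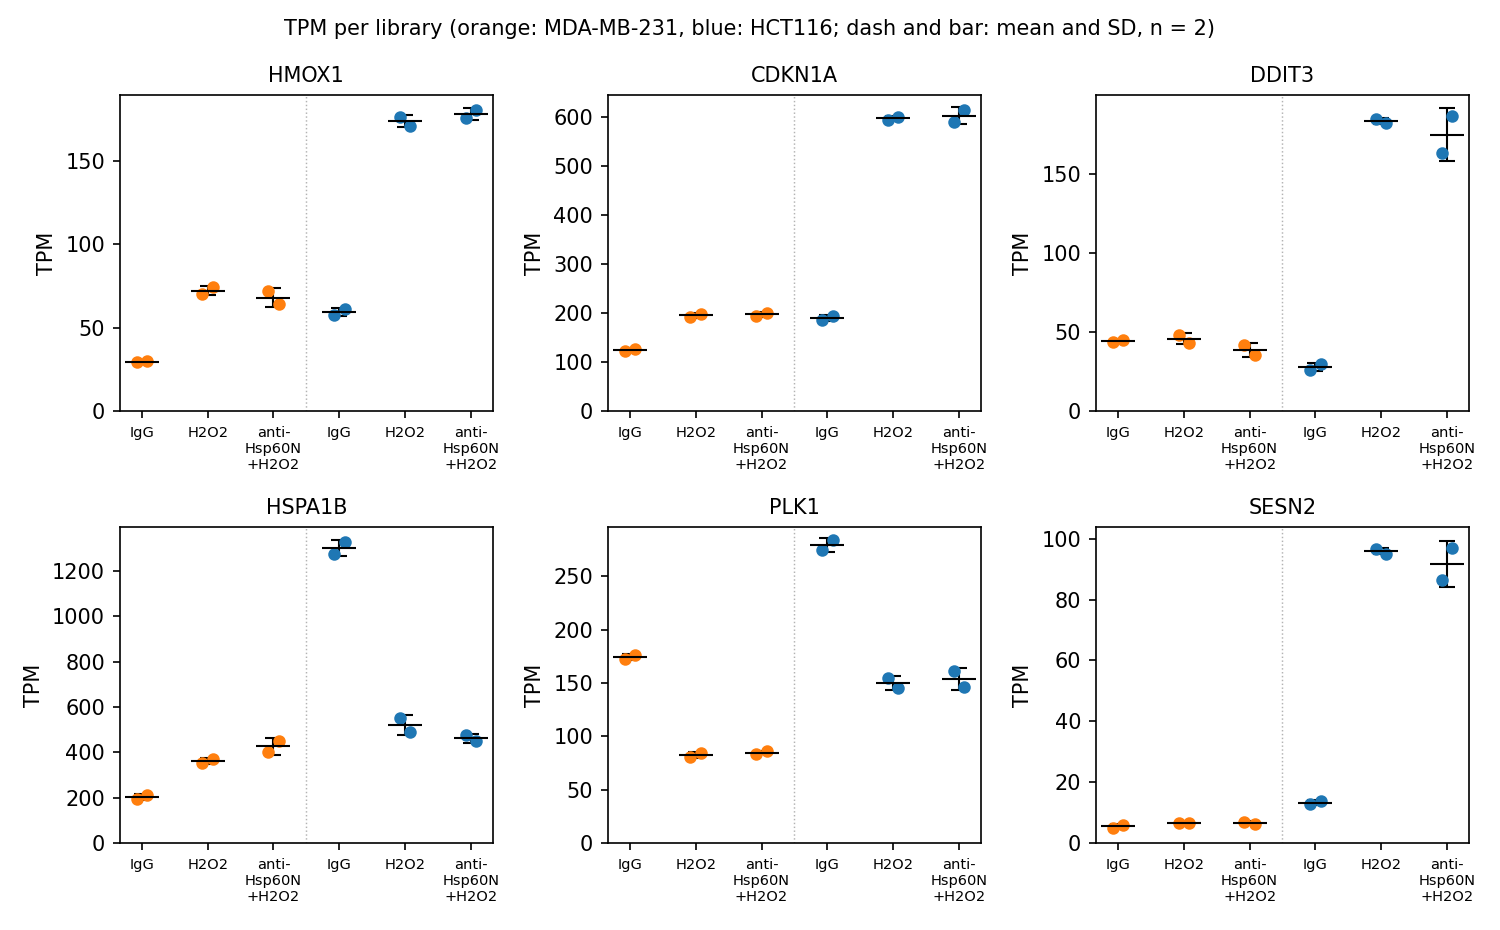
TPM of HMOX1, CDKN1A, DDIT3, HSPA1B, PLK1 and SESN2 in each library (points; orange for MDA-MB-231, blue for HCT116), with the mean (dash) and SD (bar) of 2 libraries per group. HSPA1B went from 203 to 363 TPM with H2O2 in MDA-MB-231 and from 1302 to 520.5 TPM in HCT116.

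With H2O2 in HCT116, CHAC1, a glutathione-degrading enzyme of the ATF4 response, went from 6.25 ± 0.46 TPM (SD, n = 2) to 75.4 ± 1.57 TPM (log2 3.40, SE 0.10, limma adjusted p = 3.15e-09). SESN2, a stress-induced sestrin, went from 13.3 ± 0.778 to 95.9 ± 1.08 TPM (log2 2.76), and DDIT3, the transcription factor CHOP, from 27.8 ± 2.61 to 184 ± 1.9 TPM (log2 2.68). GDF15, a stress-induced cytokine (log2 2.56), PPP1R15A, a phosphatase subunit that acts on eIF2alpha (log2 2.34), and UPP1, uridine phosphorylase (log2 2.49), rose as well. IL8, a chemokine, rose from 0.47 ± 0.0283 to 7.44 ± 0.933 TPM (log2 2.52). CDKN1A rose from 190 ± 6.45 to 598 ± 4.5 TPM (log2 1.65, SE 0.04, limma adjusted p = 2.47e-09). HMOX1 rose from 59.4 ± 2.37 to 174 ± 3.65 TPM (log2 1.53, SE 0.06, limma adjusted p = 5.04e-08). HSPA1B fell from 1302 ± 34.9 to 520.5 ± 43.7 TPM (log2 -1.32) and HSPA1A from 42.6 ± 3.72 to 17.9 ± 1.3 TPM (log2 -1.20), again with an uncertain split between the copies. FGFBP1, a carrier of fibroblast growth factors (5.16 ± 1.36 to 1.7 ± 0.318 TPM, log2 -1.18), TUBB4A, a beta tubulin (log2 -0.98), and SCO2, an assembly factor of cytochrome oxidase (log2 -0.97), were among the other genes that fell most. The pseudogene NSFP1 was called lower as well (log2 -1.30, limma adjusted p = 0.0127). The call is uncertain because of its parent gene and was lost without IgG replicate 1 (limma adjusted p = 0.0936) or H2O2 replicate 2 (0.0651).

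Of 22 ATF4 genes 19 rose and 0 fell in HCT116 (19 adjusted over the list alone), with a median of 1.02 (camera adjusted p = 2.76e-19, adjusted p = 0.0134 with an estimated correlation). TRIB3, a pseudokinase (log2 2.10), had the smallest p of the list. This was the list that also passed with an estimated correlation. Of 27 p53 targets 25 rose and 0 fell (26 over the list alone), among them TNFRSF10B, a TRAIL receptor (log2 1.59), with a median of 0.82 (camera adjusted p = 1.05e-19, adjusted p = 0.0533 with an estimated correlation). Immediate early genes rose in 19 of 24 cases (19 over the list alone), with the phosphatase gene DUSP5 at log2 1.94, ATF3 at 2.17 and MAFF at 1.70, and a median of 0.59 (camera adjusted p = 4.46e-13, adjusted p = 0.0533 with an estimated correlation). NRF2 targets rose in 14 of 27 cases and fell in 1 (16 and 1 over the list alone), with SLC7A11 at log2 2.07 and TXNRD1 at 1.40 (median 0.26, camera adjusted p = 1.39e-06, adjusted p = 0.0533 with an estimated correlation). NF-kappaB targets rose in 14 of 25 cases and fell in 1 (the same over the list alone), with RELB at log2 1.45 and NFKB2 at 0.86, both subunits of the factor (median 0.43, camera adjusted p = 2.85e-06, adjusted p = 0.0821 with an estimated correlation). Of 23 apoptosis genes 11 rose and 2 fell (14 and 2 over the list alone), with BBC3 and PMAIP1, which promote cell death, at log2 1.52 and 1.36, and BIRC3, which inhibits it, at 1.09 (median 0.25, camera adjusted p = 1.99e-05, adjusted p = 0.0533 with an estimated correlation).

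Mitosis and heat shock genes fell in HCT116. All 25 mitosis genes tested were lower (25 over the list alone), with PLK1 at log2 -0.89, AURKA at -0.85 and BIRC5, which encodes survivin, at -0.65 (median -0.53, camera adjusted p = 3.69e-16, adjusted p = 0.0688 with an estimated correlation). Of 18 heat shock genes 17 fell and 0 rose (17 over the list alone), with HSPA8, the constitutive Hsp70, going from 5116 ± 55.4 to 2746 ± 19.9 TPM (median -0.53, camera adjusted p = 1.55e-12, adjusted p = 0.0533 with an estimated correlation). Of 20 cholesterol synthesis genes 13 fell and 1 rose (the same over the list alone), with LSS at log2 -0.46 and MVD at -0.40 (median -0.30, camera adjusted p = 0.000977, adjusted p = 0.245 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 9 of 30 cases (9 over the list alone), with NDUFS3 of complex I at log2 -0.25 (median -0.09, camera adjusted p = 0.00435, adjusted p = 0.311 with an estimated correlation, and 0.328 after quantile normalization, with 5 lower). Ribosome biogenesis genes fell in 9 of 22 cases and rose in 1 (12 and 1 over the list alone), with PES1 at log2 -0.29 (median -0.12, camera adjusted p = 0.00296, adjusted p = 0.219 with an estimated correlation, and 0.0685 after quantile normalization). DNA replication genes fell in 9 of 25 cases and rose in 3 (10 and 3 over the list alone), with MCM4 at log2 -0.39, GINS2 at -0.40 and FEN1 at -0.35 (median -0.10, camera adjusted p = 0.0224, adjusted p = 0.362 with an estimated correlation). The call was lost without H2O2 replicate 1 (0.0965) and after quantile normalization (0.437). Mitochondrial chaperones and proteases fell in 9 of 17 cases and rose in 1 (the same over the list alone), with TOMM40, the outer membrane import pore, at log2 -0.41 (median -0.18, camera adjusted p = 0.0491, adjusted p = 0.219 with an estimated correlation). They lost the call without IgG replicate 1 (0.147) or H2O2 replicate 1 (0.0888), without several libraries of other groups (up to 0.0588) and after quantile normalization (0.504).

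Further lists were higher in HCT116. Hypoxia and glycolysis genes rose in 13 of 24 cases (16, with 1 lower, over the list alone), with VEGFA, an angiogenic factor, at log2 1.11 and NDRG1 at 1.15 (median 0.40, camera adjusted p = 4.26e-05, adjusted p = 0.331 with an estimated correlation). Of 6 metallothionein list genes 5 rose (5 over the list alone), with the zinc exporter gene SLC30A1 at log2 0.80 and MT1E at 0.45 (median 0.48, camera adjusted p = 0.00198, adjusted p = 0.0533 with an estimated correlation). Autophagy genes rose in 8 of 21 cases and fell in 2 (the same over the list alone), with MAP1LC3B at log2 1.83 and GABARAPL1 at 1.07, both of the autophagosome (median 0.15, camera adjusted p = 0.0032, adjusted p = 0.0533 with an estimated correlation). The non-coding list rose in 5 of 9 cases (5 over the list alone), with GAS5 at log2 1.24 and NEAT1 at 0.54 (median 0.54, camera adjusted p = 0.00296, adjusted p = 0.1 with an estimated correlation). Ribosomal protein genes rose in 13 of 30 cases (15 over the list alone), with RPL3 at log2 0.27 (median 0.12, camera adjusted p = 0.000381, adjusted p = 0.1 with an estimated correlation). The count was 9 after median-of-ratios scaling and 5 after quantile normalization, with a median of 0.07 in the latter. Transforming growth factor beta and matrix genes rose in 7 of 24 cases (7 over the list alone), with PLAU, which encodes urokinase, at log2 1.31 and its receptor gene PLAUR at 1.17 (median 0.08, camera adjusted p = 0.000405, adjusted p = 0.22 with an estimated correlation).

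The other 8 lists did not pass in HCT116, among them the unfolded protein response, in which 5 of 16 genes rose and 7 fell (median -0.14 and mean 0.02 with the test pointing down, camera adjusted p = 0.794), DNA repair with 3 of 25 higher and 8 lower (median -0.09, camera adjusted p = 0.0835), and antioxidant enzymes with 4 of 20 lower (median -0.07, camera adjusted p = 0.176). Over all genes, limma called 4592 of 13956, 2156 higher and 2436 lower, of which 146 changed by at least 2-fold, 135 up and 11 down. Without H2O2 replicate 2 the count was 3000, and without IgG replicate 2 the split was 1793 higher and 1630 lower. SNORA20 (48.4 and 52.5 TPM), SNORA51 (24.2 and 26.3 TPM), SNORA16A (21.4 and 23.2 TPM) and SNORA29 (15.3 and 16.6 TPM) were measured in both IgG libraries and listed at 0 in both H2O2 libraries. SNORA49 and SNORA67 stood at 18.7 and 22.5 TPM in both H2O2 libraries and were listed at 0 under IgG. The call for SNORA67 was lost without IgG replicate 1 or 2 (limma adjusted p = 0.0993 and 0.106) or H2O2 replicate 1 or 2 (0.0994 and 0.12).

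**Figure D2:**
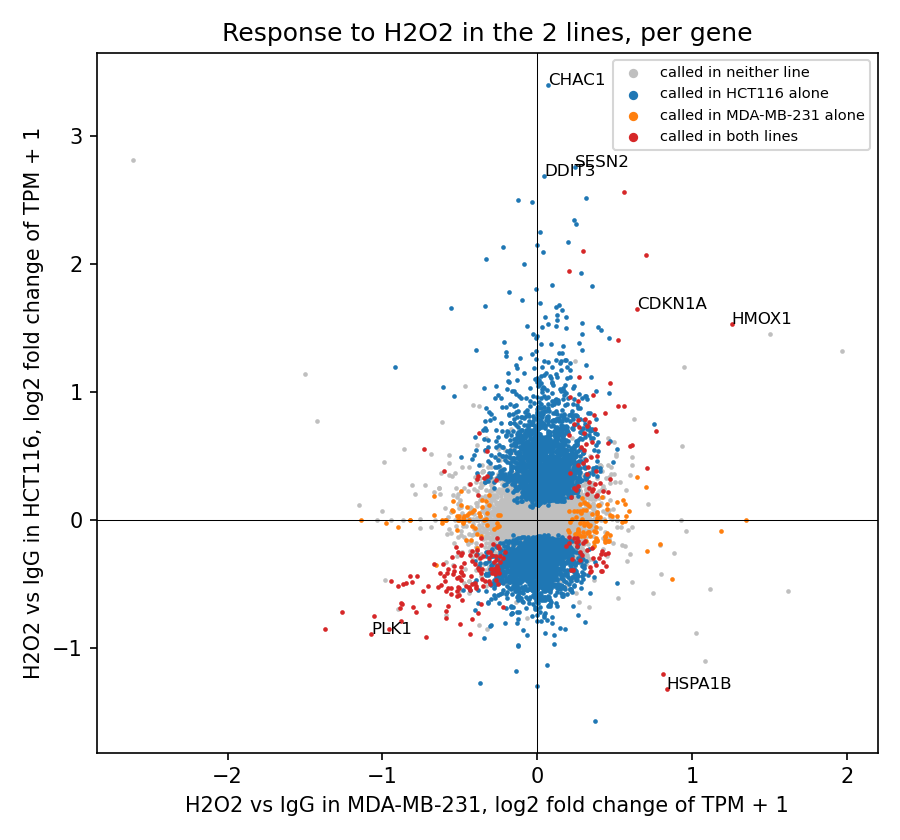
Log2 fold change of TPM + 1 for H2O2 against IgG in MDA-MB-231 (horizontal axis) and in HCT116 (vertical axis), 1 point per gene without small RNA genes, coloured by the line or lines in which limma called the gene. The points spread further along the HCT116 axis. Of the 225 genes called in both lines, small RNA genes included, 180 went the same way and 45 the opposite way. SNORA51, which is not drawn, was among the former and HSPA1B among the latter.

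The H2O2 changes of the lines overlapped in part. Of the genes called higher in MDA-MB-231, 59 were also higher in HCT116, where 28 would be expected for independent lists (Fisher's exact test, p = 8.76e-09). Of those called lower, 121 were also lower, where 33.2 would be expected (Fisher's exact test, p = 3.78e-46). Fisher's test treats genes as independent, which they are not, so these p-values do not measure the spread between samples. HMOX1, CDKN1A, TXNRD1 and SLC7A11 were higher and PLK1, KIF20A, AURKA and CCNB1 lower in both lines. A further 34 genes rose in MDA-MB-231 and fell in HCT116 (31.6 expected) and 11 did the reverse (29.4 expected). Those that rose in MDA-MB-231 and fell in HCT116 included the replication genes FEN1, GINS2, MCM3, MCM4 and MCM7, named here after their values were seen. Across the 13956 genes, which are not independent replicates, the changes of the lines correlated weakly (Pearson 0.126, Spearman 0.146). The 180 shared genes became 107 or 100 without MDA-MB-231 IgG replicate 1 or 2, and 72 or 75 without H2O2 replicate 1 or 2 of that line. The 45 genes of opposite direction became 11 or 26 and 10 or 7 without the same libraries, 21 without HCT116 H2O2 replicate 1, and 6 with each line fitted alone.

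**Figure D3:**
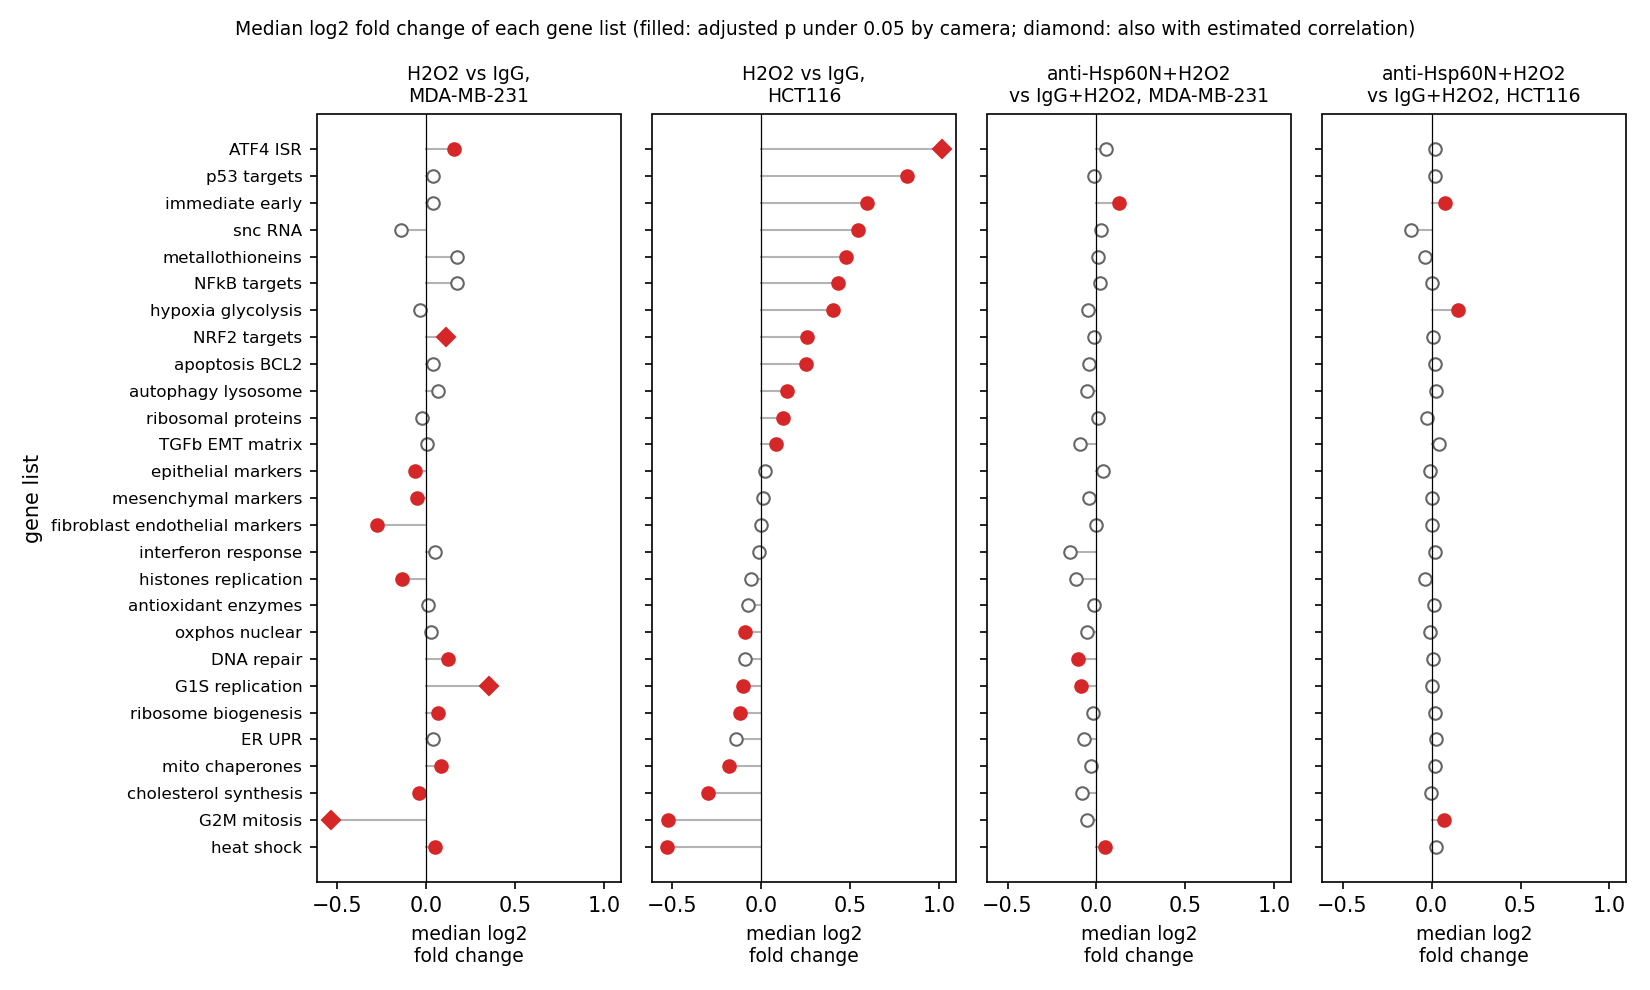
Median log2 fold change of each of the 27 gene lists in 4 comparisons (horizontal axis), with filled symbols where camera gave an adjusted p under 0.05 and diamonds where it also did with an estimated correlation. With H2O2 the ATF4 list reached 1.02 in HCT116 and 0.16 in MDA-MB-231, the heat shock list -0.53 and 0.05, and with the antibody medians lay between -0.15 and 0.15.

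With the antibody under H2O2 in MDA-MB-231, compared with IgG under H2O2, HMOX1 stood at 72.3 ± 2.72 TPM (SD, n = 2) with IgG and 68.1 ± 5.66 TPM with the antibody, CDKN1A at 195 ± 5.44 and 197 ± 4.41 TPM, and PLK1 at 82.4 ± 2.46 and 84.8 ± 1.58 TPM. CCNE2, raised by H2O2, was at log2 -0.35 (limma adjusted p = 0.242, not passing). Limma called 2 genes, both higher with the antibody and both below 5 TPM, which places them outside the naming rule. They are named because they are few. GATSL1 was at 1.83 and 2.4 TPM with the antibody and listed at 0 with IgG (limma adjusted p = 0.000254). Its near-identical copy GATSL2 had the same values with the antibody, 1.83 and 2.4 TPM, and 2.49 and 3.19 TPM with IgG, so the call is uncertain. HERC2P4, a pseudogene with close copies, went from 0.71 and 0.58 to 2.21 and 1.79 TPM (log2 0.86, limma adjusted p = 0.0449) and is uncertain too. The genes of smallest p with at least 5 TPM did not pass: TMEM158 (log2 0.37, SE 0.06), CDCA7 (log2 -0.35, SE 0.05) and C2orf76 (log2 -0.75, SE 0.11) each had a limma adjusted p of 0.132, followed by PRAF2 (log2 0.35, 0.171), and by MACROD1, DDAH2, H1FX, PTCD1, NUP133 and TMEM141 (0.199 each). At an unadjusted p under 0.05 there were 1829 genes, where chance gives 698. Genes vary together across the same few libraries, so this excess does not count genes changed by the antibody. No gene was called with each line fitted alone or at a mean TPM of at least 5.

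Of the lists, immediate early genes were higher with the antibody in MDA-MB-231 (median 0.12, camera adjusted p = 0.000127, adjusted p = 0.56 with an estimated correlation), with JUND at log2 0.52, JUNB at 0.34 and MYC at 0.14, none of which passed. Heat shock genes were higher (median 0.05, camera adjusted p = 0.00791, adjusted p = 0.657 with an estimated correlation), and DNA repair genes (median -0.10, camera adjusted p = 0.00791, adjusted p = 0.56 with an estimated correlation) and DNA replication genes (median -0.09, camera adjusted p = 0.0128, adjusted p = 0.657 with an estimated correlation) were lower. None of their members was called by limma over all genes, and adjusted over the list alone 4 of 25 replication genes were lower and 0 members of the other lists passed. In an individual test, MCM6 stood at log2 -0.26 and CCNE2 at -0.35 without passing. All 4 calls were lost without antibody replicate 2 (camera adjusted p = 0.075 for each), the replication call also without antibody replicate 1 (0.0666) or H2O2 replicate 2 (0.0993), and the repair call without H2O2 replicate 1 (0.0657). Antibody replicate 2 stood apart from its replicate on the second principal component of the line (21.1% of the variance), at 15.2 against -7.8. The H2O2 libraries were at -6.77 and -7.31. IgG replicate 2 lay on the side of antibody replicate 2, at 8.27, and IgG replicate 1 at -1.57. Fry called 1 list, the interferon response (median -0.15, fry adjusted p = 0.0177), which camera did not call (adjusted p = 0.0523).

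In HCT116 the same comparison gave 3 genes by limma. SNORA49 was at 18.7 and 22.5 TPM with IgG and listed at 0 in both antibody libraries (limma adjusted p = 4.58e-09). SNORA12 was listed at 0 with IgG and at 19.2 and 12.3 TPM with the antibody (limma adjusted p = 4.8e-07). These 2 p-values do not show an antibody effect, since this pattern of small RNA genes also arose without regard to treatment. Real group comparisons within lines had a mean of 3.67 such genes, and other pairings of the libraries 2.7. APOC1, an apolipoprotein gene at a level below the naming rule, went from 1.41 and 1.17 TPM to 0.3 and 0.35 TPM (log2 -0.79, SE 0.09, limma adjusted p = 0.0117). Of genes raised by H2O2, DDIT3 stood with IgG and antibody at 184 ± 1.9 and 175 ± 16.7 TPM, and SESN2 at 95.9 ± 1.08 and 91.7 ± 7.45 TPM. Of the other genes with at least 5 TPM, NUDT6 (log2 -0.46, SE 0.08) and OGFOD2 (log2 -0.36, SE 0.06) were both lower with the antibody. With a limma adjusted p of 0.184 they did not pass. Neither did PSMB10 (log2 -0.35) and CAMK2N1 (log2 0.35) with 0.449. At an unadjusted p under 0.05 there were 720 genes, where chance gives 698. Hypoxia and glycolysis genes (median 0.15, camera adjusted p = 0.0003), mitosis genes (median 0.07, camera adjusted p = 0.00634) and immediate early genes (median 0.08, camera adjusted p = 0.0291) were higher with the antibody, with an adjusted p = 0.967 with an estimated correlation for each, 0 members called over all genes and 0 adjusted over the list alone. All 3 calls ended without H2O2 replicate 1 (0.0509, 0.526 and 0.0509) or antibody replicate 1 (0.654, 0.707 and 0.0886). That for immediate early genes also ended without H2O2 replicate 2 (0.27) or antibody replicate 2 (0.213), and fry called 0 lists.

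**Figure D4:**
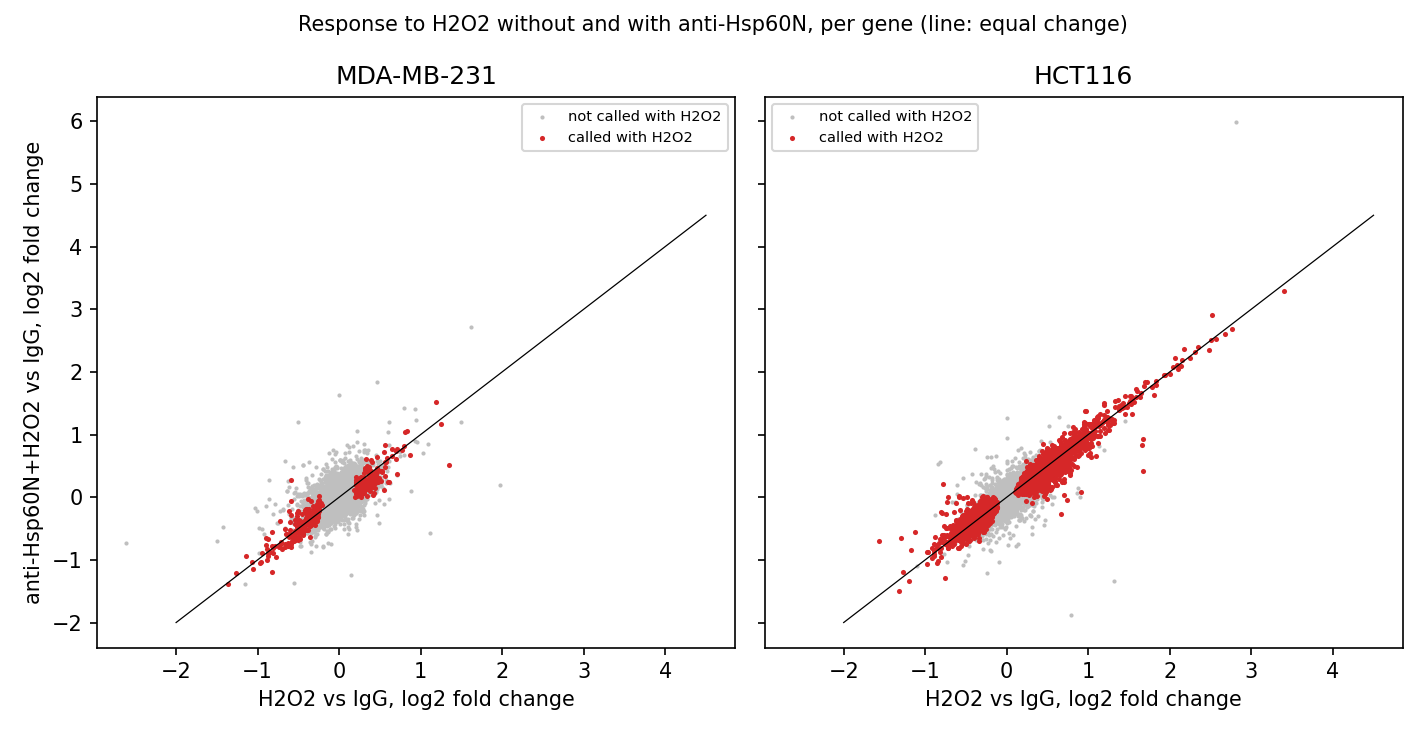
Log2 fold change of TPM + 1 against IgG, for H2O2 with IgG (horizontal axis) and H2O2 with anti-Hsp60N (vertical axis) in each line, 1 point per gene without small RNA genes, red where limma called the gene with H2O2. Over all genes drawn the changes correlate at 0.637 in MDA-MB-231 and 0.916 in HCT116, and both axes share the IgG libraries.

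Compared with IgG alone, H2O2 with the antibody gave 475 called genes in MDA-MB-231 (210 higher and 265 lower) and 4792 in HCT116 (2344 higher and 2448 lower) by limma. After median-of-ratios scaling the split was 239 higher and 370 lower in MDA-MB-231, and 2299 and 2721 in HCT116. In MDA-MB-231 HMOX1 rose by log2 1.17, HSPA1B by 1.06, HSPA1A by 1.05 and TNFRSF6B, a decoy receptor, by 0.88 (limma adjusted p = 0.00547, lost without IgG replicate 2 with 0.0702). KIF20A (log2 -1.38), PIF1 (log2 -1.21) and TMEM71 (log2 -1.19) fell. The read-through gene EEF1E1-MUTED was called as well (limma adjusted p = 0.0461) and lost without any 1 of the 4 libraries compared (up to 0.178). In HCT116 the largest changes were of small nucleolar RNA genes and of RPL21, which has many near-identical copies. Mitosis genes were lower in MDA-MB-231 (22 of 25 fell, 25 over the list alone, median -0.56, camera adjusted p = 4.09e-38, adjusted p = 0.0423 with an estimated correlation). NRF2 targets were higher (8 of 27 rose, 16 over the list alone, median 0.15, camera adjusted p = 1e-08, adjusted p = 0.0423 with an estimated correlation). ATF4 genes rose in 19 of 22 cases in HCT116 (20 over the list alone, median 1.03, camera adjusted p = 1.9e-18, adjusted p = 0.0152 with an estimated correlation). The count in MDA-MB-231 was 301 or 145 without IgG replicate 1 or 2 and 163 without antibody replicate 2, and that in HCT116 was 2953 without antibody replicate 2 (1530 higher and 1423 lower).

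Of the genes called with H2O2 in MDA-MB-231, 84 of 181 higher and 142 of 190 lower were also called the same way with antibody and H2O2 (2.72 and 3.61 if the lists were independent). In HCT116 these were 1841 of 2156 and 1927 of 2436 (362 and 427). 0 genes were called in opposite directions in either line. Both comparisons share the IgG libraries, so they are not independent and overlap without any effect. Simulated sets without effects gave correlations of 0.395 to 0.615 between the 2 changes for this reason. The measured correlation was 0.611 in MDA-MB-231, inside that range, and 0.867 in HCT116, above it. Without small RNA genes it was 0.637 in MDA-MB-231 and 0.916 in HCT116, against 0.451 to 0.572 simulated. In HCT116 the 2152 genes raised by H2O2, leaving out small RNA genes, had a median of 0.41 without and 0.41 with the antibody. Of these genes, 95.5% differed by less than 0.25 log2 between antibody and IgG. In MDA-MB-231, 91.7% of the 181 raised and 92.6% of the 188 lowered genes were within 0.25. The medians were 0.35 without and 0.25 with the antibody for raised genes and -0.45 and -0.43 for lowered genes. These genes were picked by their change in the same H2O2 libraries, so a smaller median with the antibody can arise from the selection alone, and the value without an effect was not computed. The 95% interval of a single gene's antibody effect reached a median of 0.19 log2 to either side. A change of 0.25 log2 would undo most of a rise of 0.35, the median of the raised genes in MDA-MB-231. The share of all genes within 0.25 is not given here. The percentages within 0.25 therefore cannot show that the response persisted. Across genes, the H2O2 change and the antibody change correlated at -0.397 in MDA-MB-231 and -0.208 in HCT116. This compares with a mean of -0.494 (range -0.605 to -0.343) in 100 simulated sets without effects that shared the H2O2 libraries. Those sets held no H2O2 change, and a H2O2 change that the antibody leaves alone would weaken the correlation. The correlations therefore cannot show whether the antibody reversed part of the H2O2 change. The covariance was -0.0139 in MDA-MB-231 and -0.0125 in HCT116 against -0.00961 simulated, a difference of -0.00428 and -0.00292. In MDA-MB-231 the difference amounts to 22.2% of the variance of the H2O2 change that is left once the spread between libraries is subtracted. With each H2O2 library used for 1 of the 2 changes only, the value in MDA-MB-231 was 33.7% or -1.55%, depending on the library. Without small RNA genes, a setting chosen after seeing the data, these values were 27.3% and 5.51%, and the covariance difference was -0.00265 (SD 0.000381 in simulated sets, in which genes vary independently). In HCT116 without these genes the difference was 0.00112. The direction in MDA-MB-231 thus turned with the library when small RNA genes were kept, and the size depended on the library in either case.

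HSPD1, the gene of Hsp60, stood at 650 ± 23 TPM under IgG, 698 ± 15.5 TPM with H2O2 and 666 ± 10.2 TPM with H2O2 and antibody in MDA-MB-231 (SD, n = 2). In HCT116 it stood at 1913 ± 73.4, 1687 ± 87.9 and 1777 ± 3.8 TPM. It was higher in HCT116 under IgG (log2 1.56, limma adjusted p = 9.84e-11). With H2O2 the change was log2 0.10 in MDA-MB-231 (limma adjusted p = 0.308) and -0.18 in HCT116 (limma adjusted p = 0.0147). The latter was lost without HCT116 IgG replicate 1 (0.0808) or H2O2 replicate 1 (0.121) and after quantile normalization (0.0709). With the antibody under H2O2 it was log2 -0.07 in MDA-MB-231 (limma adjusted p = 0.558) and 0.08 in HCT116 (0.92). Against IgG alone it was 0.04 (0.751) and -0.11 (0.114). Between the lines the H2O2 effect differed by log2 -0.28 (limma adjusted p = 0.0172), a call lost in 5 settings, among them leaving out MDA-MB-231 IgG replicate 1 (0.0629), MDA-MB-231 H2O2 replicate 1 (0.0687) or HCT116 H2O2 replicate 1 (0.0643). The antibody effect differed by 0.14 (limma adjusted p = 0.405).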

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

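The differences between lines in the next 4 paragraphs come from interaction tests planned before the data were examined, while the tests that weigh explanations after them were chosen only after the results were seen. A positive value means a higher change in HCT116 than in MDA-MB-231.

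The H2O2 effect differed between the lines for 2423 genes by limma (1067 more positive in HCT116 and 1356 more negative, Benjamini-Hochberg adjusted p under 0.05). The balance turned to 1249 and 1178 after median-of-ratios scaling, 1194 and 1139 after quantile normalization, and 940 and 721 without MDA-MB-231 IgG replicate 1. The count was 1371 or 1251 without MDA-MB-231 H2O2 replicate 1 or 2, and 1514 or 1571 without HCT116 H2O2 replicate 1 or 2. Genes with a more positive change in HCT116 were CHAC1 (log2 3.33, adjusted p = 2.13e-07), DDIT3 (2.64), UPP1 (2.52), SESN2 (2.52), IL8 (2.1995), PPP1R15A (2.10), GDF15 (2.003), SLC7A11 (1.37) and CDKN1A (1.003, adjusted p = 4.96e-06). ALPP (0.85), PIF1 (0.54), KIF20A (0.52) and NEK2 (0.47) fell more in MDA-MB-231, and HMOX1 differed by 0.28 (adjusted p = 0.0481). More negative in HCT116 were TUBB4A (log2 -0.85), PINLYP (-0.98), FGFBP1 (-1.04), SCO2 (-1.08), and the near-identical HSPA1A (-2.01) and HSPA1B (-2.16, adjusted p = 8.41e-07). ALPP and PINLYP in HCT116, and TUBB4A and FGFBP1 in MDA-MB-231, stood below 1 TPM in every library, so their differences do not show a different response of the lines. SNORA20 (50.5 TPM on average) and SNORA16A (22.3 TPM) in HCT116 IgG, and SNORA49 (20.6 TPM) in HCT116 H2O2, were listed at 0 in other groups and differed too.

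Among lists, the ATF4 genes differed by a median of 0.86 (camera adjusted p = 3.15e-19), and this was the list that also passed with an estimated correlation (0.0136). The p53 targets differed by 0.81 (camera adjusted p = 1.04e-20; adjusted p = 0.0741 with an estimated correlation), immediate early genes by 0.57 (7.07e-13; 0.0821) and NF-kappaB targets by 0.47 (3.04e-05; 0.0932). Positive differences by camera were also seen for the non-coding list (0.74, adjusted p = 0.000392), hypoxia (0.50, 4.7e-06), fibroblast or endothelial markers (0.26, 0.0312), apoptosis (0.22, 0.000218), metallothioneins (0.21, 0.0176), NRF2 targets (0.20, 0.00102), transforming growth factor beta genes (0.17, 7.18e-06), ribosomal proteins (0.14, 7.97e-05) and autophagy (0.0792, 0.012). With an estimated correlation these had a camera adjusted p = 0.0834 for the non-coding list, NRF2 targets, apoptosis, ribosomal proteins and autophagy. It was 0.0932 for metallothioneins, 0.114 for transforming growth factor beta genes, 0.165 for fibroblast or endothelial markers and 0.264 for hypoxia. The 5 fibroblast or endothelial markers had a median of 0 in HCT116 and -0.27 in MDA-MB-231, with 0 called in either. Their difference does not show a response in HCT116.

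Negative differences by camera were seen for heat shock genes (median -0.61, adjusted p = 8.5e-15, and adjusted p = 0.0777 with an estimated correlation), DNA replication (-0.37, 1.15e-10, and 0.0821 with an estimated correlation), ribosome biogenesis (-0.24, 0.00022, 0.114), mitochondrial chaperones and proteases (-0.23, 0.00366, 0.0834), DNA repair (-0.20, 0.0011, 0.123), cholesterol synthesis (-0.20, 0.0344, 0.404) and oxidative phosphorylation (-0.15, 0.0107, 0.315).

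The antibody effect under H2O2 differed between lines for 4 genes by limma, and for 0 lists. Such low counts do not show that the effect was alike in the lines. Across the 13956 genes, which are not independent replicates, the antibody changes of the lines correlated at -0.134 (Pearson) and -0.189 (Spearman). The genes called the same way in both lines numbered 0. SNORA49, at 20.6 TPM on average in HCT116 H2O2 (adjusted p = 1.77e-07), and SNORA12, at 15.8 TPM in HCT116 with the antibody (adjusted p = 1.76e-05), were listed at 0 in other groups. GATSL1 (adjusted p = 0.00271) is the gene whose copy GATSL2 has the same values with the antibody. The other was LOC441461, a low gene chosen after its values were seen.

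In small nucleolar RNA genes, both libraries of 1 group were listed at 0 while both libraries of another stood above 10 TPM. Of 160 replicate pairs with such a gene at 10 TPM or more in 1 library, 59.4% had 0 in the other, against 0.00768% for other genes, which fits unstable estimates for very short genes. Of 56 cases at 10 TPM or more in both libraries, 57.1% shared the ratio between the libraries with another small RNA gene within 1%, against a median of 7.14% with exchanged values, which fits values that stand for 1 or a few reads. Real group comparisons within lines had a mean of 3.67 such genes, other pairings of the libraries 2.7, so the test could not tell a treatment effect from none.

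H2O2 changed fewer genes in MDA-MB-231 than in HCT116. A larger spread between MDA-MB-231 libraries was not seen, its median residual SD being 0.982 times that of HCT116. The fit used 1 shared spread per gene for both lines, with a median SE of 0.0861 log2 for H2O2 in each. Both values argue against a larger spread as the reason for the lower count. Over all genes, opposite calls could not tell the same response at a lower strength from another one. They were 12.1% of MDA-MB-231 calls, but 6.98% with each line fitted alone. The ATF4 list had a median of 0.16 in MDA-MB-231 and 1.02 in HCT116. The mitosis list had -0.54 and -0.53, with 22 and 25 of 25 genes lower, which argues against a lower strength for these mitosis genes. For the DNA replication list, which rose in MDA-MB-231, the median difference of -0.37 log2 argues against the same response at a lower strength. It leaves that explanation open, since the difference had a camera adjusted p = 0.0821 with an estimated correlation and the fall in HCT116 0.362. The lines differ in p53 status by background knowledge, and the p53 target difference of 0.81 log2 could not be tied to it, with 1 line of each kind and a different medium for each.

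DNA replication genes rose with H2O2 in MDA-MB-231 and lay lower with the antibody. The highest list median over the 4 pairs of libraries, less the median of all genes, was -0.0479 log2 and so below 0 in every pair, yet chance in libraries that all list members share could not be told from an antibody effect. The list had an adjusted p = 0.657 with an estimated correlation. No technical explanation beyond shared libraries was tested.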

How the results depend on the processing

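Leaving out small RNA genes and exchanging replicate numbers were chosen after seeing the data, and the other alternatives before. The totals below pool unlike settings. Leaving out 1 library, often one outside the comparison, gave 423 of the list cases kept and 2504 of the named gene cases kept. With an estimated correlation, camera kept 4 list calls and lost 35. Over all settings, results of gene lists kept direction and side of the threshold in 787 cases, lost the call in 108 and reversed in 0. Results of named genes kept it in 4520 cases, lost the call in 174, gained it in 16 and reversed in 1: HSPD1 in H2O2 with antibody against IgG in MDA-MB-231, not called with all libraries, was at log2 -0.000821 without IgG replicate 1 and ranged from there to 0.0714 over all libraries left out. The cause was not tested.

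With each library left out in turn, which lowers the number of samples, H2O2 against IgG gave 116 to 434 genes in MDA-MB-231 and 3000 to 4650 in HCT116, and with the antibody against IgG 145 to 551 and 2953 to 4817. The antibody under H2O2 gave 1 to 3 genes in MDA-MB-231 and 3 to 7 in HCT116. The H2O2 effect differed between lines for 1251 to 2335 genes, the antibody effect for 3 to 6. The lists called with H2O2 were 8 to 13 and 17 to 19, and with the antibody 0 to 6 and 0 to 3. Genes changed the same way by H2O2 in both lines were 72 to 199. The covariance of the H2O2 and antibody changes, less the simulated value, ranged from -0.0101 to -0.00398 in MDA-MB-231 and from -0.0119 to 4.7e-05 in HCT116.

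With each line fitted alone, which leaves fewer samples to estimate the spread, MDA-MB-231 had 86 genes with H2O2, 101 with H2O2 and antibody and 0 for the antibody under H2O2, and 51 genes changed the same way in both lines. At a mean TPM of at least 5, which tests fewer genes, the antibody under H2O2 gave 0 genes in MDA-MB-231 and 1 in HCT116, and its effect differed between lines for 0. With a pseudocount of 5 it gave 1 gene in MDA-MB-231, and without the variance trend 5 in HCT116; the cause was not tested. Without small RNA genes it gave 1 gene in HCT116 and differed between lines for 2, since small RNA genes made up the rest. With an estimated correlation, camera called 3 and 1 lists with H2O2 in MDA-MB-231 and HCT116 and 0 and 0 with the antibody, and fry called 1 and 0 with the antibody.

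The covariance difference in MDA-MB-231 was -0.0108 with a pseudocount of 0.1, -0.0019 with 5, -0.00163 without a filter and -0.00265 without small RNA genes. In HCT116 it was -0.0121 with a pseudocount of 0.1, -1.27e-05 with 5, -0.000513 at a mean TPM of at least 5 and 0.00112 without small RNA genes. The cause was not tested.

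Equal replicate numbers were not taken to pair samples, since not every pair of groups passed a correlation of 0.1, and in MDA-MB-231 this stays open. Deviations of equally numbered libraries correlated at 0.104, 0.164 and 0.012 in MDA-MB-231 and -0.127, 0.0552 and 0.0458 in HCT116. With the number as a block, H2O2 gave 274 genes in MDA-MB-231 and 4396 in HCT116, and the antibody 1 and 2. The block ended the list calls for mitochondrial chaperones in MDA-MB-231 (0.0595) and HCT116 (0.0583) and for ribosome biogenesis in MDA-MB-231 (0.0595). It also ended the calls for TRAF3IP2-AS1 (0.0571), MSH6 (0.0558) and MVK (0.0662) with H2O2, and for EEF1E1-MUTED (0.0619) with H2O2 and antibody, in MDA-MB-231. With exchanged numbers in HCT116 IgG, 4731 genes were called with H2O2 in HCT116. Depth is unknown, so what it limits could not be measured. The simulated recovery of 18% at 0.25 log2 applies to H2O2 in MDA-MB-231 with few genes changed. In HCT116 the smallest change called with H2O2 was 0.10 log2, so the 18% does not hold there.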

Other observations

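Gene families, defined by symbol stems and compared after the main results were seen, added groups beside the fixed lists, and the genes named here were chosen after their values were seen. With H2O2 in HCT116, genes of the mitochondrial ribosome fell: 33 of 49 MRPL genes were lower and 0 higher by limma (median -0.23, camera adjusted p = 1.18e-07 over 151 families, adjusted p = 0.624 with an estimated correlation), with MRPL46 at log2 -0.50 and MRPL36 at -0.44, and 17 of 30 MRPS genes were lower (median -0.22, camera adjusted p = 0.000644, adjusted p = 0.624 with an estimated correlation). Kruppel-like transcription factors rose, 10 of 14 being higher (median 0.45, camera adjusted p = 0.000159, adjusted p = 0.624 with an estimated correlation), with KLF5 at log2 1.03 (SE 0.08, limma adjusted p = 8.64e-06) and KLF4 at 0.94 (SE 0.08). Of 10 genes of the IRF stem, 7 rose (median 0.33, camera adjusted p = 0.0156, adjusted p = 0.752 with an estimated correlation), with IRF7, an inducer of interferon genes, at log2 0.80. Of 13 SNHG genes, hosts of small nucleolar RNAs, 10 rose (median 0.30, camera adjusted p = 0.00216, adjusted p = 0.752 with an estimated correlation). The fixed lists already held KLF2, KLF4, KLF6, IRF1, IRF7, IRF9 and SNHG1. None of the directions of these 5 families in HCT116 changed under median-of-ratios scaling or quantile normalization.

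Among the genes called in opposite directions by H2O2 in the lines, KDM5B, a histone demethylase, fell in MDA-MB-231 by log2 0.33 and rose in HCT116 by 0.54, and ARTN, a neurotrophic factor, fell by 0.73 and rose by 0.55. FKBP5, a cochaperone of Hsp90, rose by 0.42 in MDA-MB-231 and was at -0.24 in HCT116. PPIF, the mitochondrial cyclophilin, was at 0.25 and -0.17. The 45 genes of opposite direction, from which these were picked, became 7 to 26 without any 1 of the 4 MDA-MB-231 libraries compared, 21 without HCT116 H2O2 replicate 1, and 6 with each line fitted alone.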
